A study of Mus musculus with 2 samples.

How the data were processed

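ELF1 ChIP-seq was carried out on 2 biological replicates of the CH12.LX mouse B-cell lymphoma line, per the labels, and both form 1 group. The deposited files were peak lists in the narrowPeak format. Per the deposited README text, the relaxed list of each replicate was derived from that replicate's mm10 alignments and a control, the pooled relaxed list from both, and the optimal and conservative lists from these relaxed lists by the irreproducible discovery rate, which ranks peaks by how well replicates agree. The mm9 list was derived from both replicates' mm9 alignments. The aligner, the peak caller and their versions are not given in the sources used here. Column 7 of each deposited list is the peak signal as the caller gave it; its scale is not given, it differs between lists, and it was used to rank peaks within a list, and between the replicates' lists only to describe their correlation and ratio. Columns 5 and 9 of the deposited mm10 lists were taken as scores, because column 9 held values below 0, and the mm9 list's column 9 as the −log10 of a q-value by the deposited format. None of these columns entered a test. The peaks of the optimal, conservative and pooled lists were called on both replicates together, so the replicates were compared with each other through their own relaxed lists, a comparison tested after the data were seen. The planned values for the optimal peaks are given as a description. All 3 relaxed lists had 300000 entries and so hold peaks and background alike. Per-peak read counts were not used here, and no p-value between samples was possible.

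The optimal list was compared with the 29086 strongest entries of each replicate, since 29086 is its own length. Summits within 100 bp counted as shared. Random expectation came from 1000 seeded shifts of 50 to 500 kb on the same chromosome, and from 50 shifts for each alternative of the promoter share. Alternatives of replicate agreement used 20 shifts, or 5 for overlaps.

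For mm10 lists, start sites were the 5′ ends of genes in a RefSeq table of assembly GRCm38.p6, which has no strand. Strand was looked up by symbol or synonym on the same chromosome in GENCODE M1, whose coordinates were not used for mm10. Of 21887 protein-coding genes 20576 (94.0%) got a strand, 18392 by symbol and 2184 by synonym. One 5′ end per gene was used, so alternative start sites were missed. For the mm9 list, all GENCODE M1 transcript start sites and the NCBIM37 sequence, the same build, were used. Coordinates are 1-based and were not converted between builds. No mm10 sequence was used here, so every motif test was run on the mm9 list and not, as planned, on the optimal list, and the CpG strata were made for mm9 promoters.

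A gene was bound when an optimal summit lay within 1 kb of its 5′ end. A distal peak lay 2 to 50 kb from the 5′ end and over 2 kb from every start site and from both ends of genes of unknown strand. Each of 18 gene lists was compared with all other protein-coding genes on chromosomes with peaks (20557 genes) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes that share a promoter peak and neighbouring peaks are not independent, so these p-values are too small to an unknown degree. The lists were B cell identity and signalling, antigen presentation, class switching and double-strand break repair, ETS family, interferon signalling, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, DNA replication, pre-mRNA splicing, T cell, myeloid, erythroid and megakaryocyte, hepatocyte, neuron and skeletal muscle markers, and olfactory and vomeronasal receptors. Rev7, Mx1, Hbb-bs and Hbb-bt had no match. Motif words were sought on both strands within 50 bp of the summit and in windows of the same length 500 bp to each side, by the exact McNemar test. The trend over 10 deciles used a permutation test with 100000 resamples in place of full enumeration. Divergent pairs were also counted once each and compared with 1000 sets of random pairs of other genes, a test added after the data were seen. Stratified tests were Cochran-Mantel-Haenszel tests.

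The genes named were fixed by a rule before the data were examined: the 12 genes with the strongest promoter peaks, 4 members of each list with the strongest promoter peak (every bound member where at most 5 were bound) and up to 3 unbound members in alphabetical order where over 80% were bound, every ETS family and B cell gene with its status, and the 5 strongest peaks over 10 kb from every start site. Some items that the rule names are left out of the text. Genes named for a shared peak or for a distal peak without a promoter peak, and the 16 forms of the ETS site, were chosen after their values were seen.

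On simulated data over all 20576 genes with a strand, lists planted at an odds ratio of 4 were called in 46% of 100 simulations with 20 genes, 86% with 40 and 100% with 80. At an odds ratio of 0.25 the shares were 21%, 65% and 99%. So short lists could be missed. Of unchanged lists, 0.278% were called. Alternatives covered distances, overlap rules, peak sets, motif forms, windows, strata and each replicate alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0, samtools 1.23.1, blastn 2.17.0 and matplotlib 3.10.9 were used.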

Results

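ELF1 is a transcription factor of the ETS family, whose members bind DNA around a GGAA core. The data were ChIP-seq peak lists for ELF1 in CH12.LX, a mouse B-cell lymphoma line grown in culture. ChIP-seq sequences the DNA fragments that an antibody against a chromatin protein brings down, and a peak is a place where such fragments pile up. There was 1 group of 2 biological replicates, with no second condition, so the comparisons below are between replicates, between peak lists and between classes of genes or sequences. The deposited lists on the mm10 build held 29086 optimal peaks, 27399 conservative peaks and 300000 relaxed entries for each replicate and for both replicates pooled. An older list of both replicates together on the mm9 build held 18804 peaks. Read depth is unknown from these lists, and intervals given for shares cover counting error only.

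The first question was how far the replicates found the same sites. The strongest ELF1 sites were found in both replicates. The peak of highest signal lay at the promoter of Fam172a, with a signal of 622 in the pooled list, 291 in replicate 1 and 335 in replicate 2. The peak at Edem2, which acts in the degradation of misfolded glycoproteins, had signals of 612, 311 and 302 in the same order. The peak at Ciao3, a member of the cytosolic iron-sulfur assembly machinery, had 609, 311 and 304. Of the 29086 strongest entries of replicate 1, 19005 (65.3%, 95% exact interval 64.8% to 65.9%) had a summit within 100 bp of one of the 29086 strongest of replicate 2, and 19006 (65.3%) the other way round. Entries of replicate 1 shifted at random by 50 to 500 kb on their chromosome gave 0.540% on average and 0.691% at most over 1000 shifts (permutation p = 0.001, the smallest these shifts can give). The optimal peaks were called on both replicates together and chosen by the irreproducible discovery rate, so their shares describe that list and test nothing. Of these peaks, 85.4% had a summit within 100 bp in both full relaxed lists, so not all were found in each replicate. Of the 29086 optimal peaks, 18282 (62.9%, 95% exact interval 62.3% to 63.4%) had a summit within 100 bp of a summit among the 29086 strongest peaks of each replicate. Taken singly, 73.8% were among the strongest of replicate 1 and 78.3% among the strongest of replicate 2. In the full relaxed lists of both replicates, 98.4% of the strongest decile of the optimal peaks had a summit within 50 bp, 67.8% of the seventh decile, 52.0% of the ninth and 18.5% of the weakest. Across the 24844 optimal peaks with a summit within 100 bp in both full lists, log2 signal had a Pearson correlation of 0.856 and a Spearman correlation of 0.812. These values run across peaks, which are not independent replicates. Replicate 2 gave signals 1.33 times those of replicate 1 at the median peak, on scales that are not given and can differ between the lists, and the SD of the log2 difference was 0.68.

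**Figure D1:**
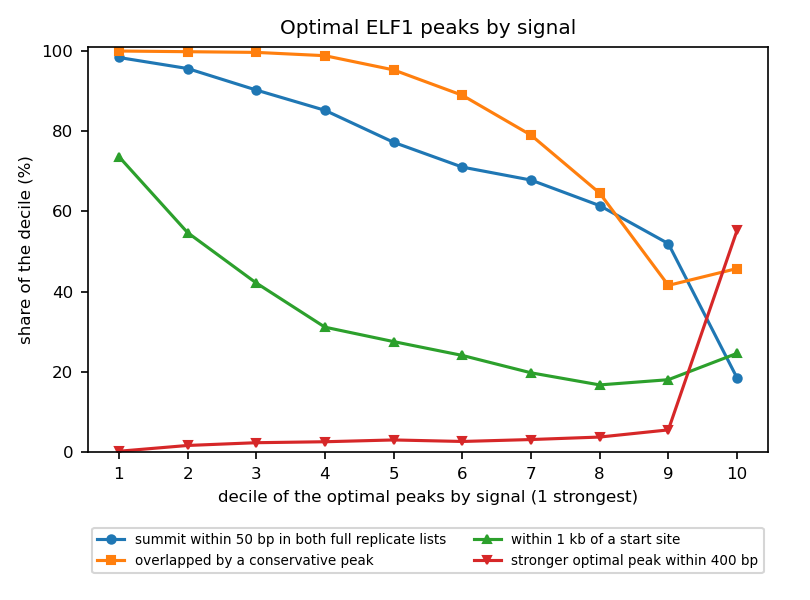
Share of each decile of the 29086 optimal peaks, ranked by signal, that had a summit within 50 bp in the full lists of both replicates, was overlapped by a conservative peak, lay within 1 kb of a start site, or lay within 400 bp of a stronger optimal peak. The share with a summit in both replicates fell from 98.4% in the strongest decile to 18.5% in the weakest, where 55.3% lay beside a stronger peak.

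The optimal and conservative lists of the same libraries differed among weak peaks. Promoter sites such as those of Fam172a, Edem2 and Ciao3 lay in the strongest decile, of which 100% was overlapped by a conservative peak. Of all optimal peaks, 23662 (81.4%, 80.9% to 81.8%) were overlapped by at least 1 bp. The share was 98.7% in the stronger 14543 peaks and 64.0% in the rest. The 5424 peaks of the optimal list alone had a median signal of 22.0 against 48.4 for shared peaks, and lay at promoters less often, 18.5% against 36.6% (Fisher's exact test, two-sided, odds ratio 0.392, p = 1.26e-156). The conservative list was not contained in the optimal one, since 3832 of its peaks (14.0%) overlapped no optimal peak, with a median signal of 22.0.

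ELF1 peaks were concentrated at gene starts. Behind the 3 genes named above, the strongest promoter peaks belonged to Slc38a10, Atg7, Zranb2, Vps41, Vta1, Gatad2a, Sec31a, Sirt7 and Tfg, with signals from 587 down to 560. Atg7 acts in autophagy, Sec31a is part of the COPII vesicle coat, and Vps41 and Vta1 act in endosomal transport. The summits of these 12 genes lay 7 to 111 bp from the annotated 5′ end. In mm10 coordinates the Fam172a peak spanned chromosome 13 from 77708492 to 77708876, the Edem2 peak chromosome 2 from 155729258 to 155729624, and the Ciao3 peak chromosome 17 from 25773581 to 25773916. Of the optimal peaks, 9672 (33.3%, 95% exact interval 32.7% to 33.8%) had their summit within 1 kb of a start site, 9.17 times the 3.63% of shifted summits (permutation p = 0.001, the smallest that 1000 shifts can give). Promoter peaks had a median signal of 67.3 and the others 33.8. The promoter share was 73.7% in the strongest decile, 16.7% in the eighth and 24.6% in the weakest. A further 48.6% of the peaks lay 2 to 50 kb from the nearest start site, and 5.72% lay farther away.

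Strong peaks were also found over 10 kb from the start sites used here. With 1 5′ end per gene, a peak within gene bounds can lie at an alternative start site, which was not checked. Of the optimal peaks over 10 kb from every start site, the strongest had a signal of 493 and lay on chromosome 6 from 119388679 to 119388983, within the bounds of Adipor2, an adiponectin receptor gene, 28.9 kb from its 5′ end. Another lay within the bounds of Gm10044 on chromosome 14 from 7773974 to 7774340 (signal 492), and another within Mrps23 on chromosome 11 from 88204236 to 88204539 (467). A further peak lay outside gene bounds on chromosome 16 from 93914204 to 93914517 (458), 30.5 kb from the 5′ end of Chaf1b, which encodes a chromatin assembly factor subunit. Each of these 4 peaks was present in both replicates, with signals of 211 to 248 in replicate 1 and 247 to 258 in replicate 2. The peak within 1 kb of the 5′ end of Mrps23 had a signal of 23.4, below the 467 of the peak within its bounds.

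The next comparison asked which groups of genes had ELF1 at the promoter. Promoters of genes for basic cell functions were bound most often. Mitochondrial ribosomal protein genes were bound in 72 of 77 cases (93.5%) and cytosolic ribosomal protein genes in 77 of 83 (92.8%), against about 40.1% of other protein-coding genes. Proteasome genes were bound in 35 of 39 cases, DNA replication genes in 32 of 37, oxidative phosphorylation genes in 74 of 87 and pre-mRNA splicing genes in 36 of 44. The adjusted p of these 6 lists lay between 5.87e-23 for cytosolic ribosomal proteins and 6.33e-08 for splicing (Fisher's exact test, two-sided, Benjamini-Hochberg over 18 lists). The strongest peaks in these lists were at Sf3b5, a splicing factor subunit gene (signal 557), Ndufb9 of respiratory complex I (547), Mrps33 (531), Rpl27 (515), Gins3 of the replicative helicase (483) and Psmb3 of the proteasome (479). Others of high signal were Rps12 (510), Ndufa13 (499), Rpl38 (485), Rps26 (478), Cdc45 (447), Mrpl50 (437), Prpf19 (429), Ndufs7 (429), Cdc6 (416), Mrpl10 (413), Sdhb (409), Psmd9 (402), Snrpc (389), Mrpl27 (388), Psmc2 (373), Sf3b2 (354), Psmd2 (344) and Rpa3 (340). Within strata of equal promoter CpG content, on the mm9 list, these 6 lists kept their calls with lower odds ratios. The values went from 10.3 without strata to 4.35 for cytosolic and from 24.3 to 10.7 for mitochondrial ribosomal proteins. They went from 10.9 to 3.71 for splicing, 19.6 to 7.48 for DNA replication, 21.9 to 14.6 for the proteasome and 6.74 to 4.30 for oxidative phosphorylation. Members without a peak within 1 kb of the 5′ end used included Rpl10l, Rpl17 and Rpl19 among cytosolic ribosomal protein genes and Mrpl18, Mrpl22 and Mrpl24 among mitochondrial ones. Atp5d, Atp5g3 and Cox4i2 of oxidative phosphorylation and the proteasome genes Psma6, Psma8 and Psmb11 were also unbound. The same held for the replication genes Lig1, Orc1 and Orc4 and the splicing genes Hnrnpk, Hnrnpu and Srsf1. Several of the strongest peaks also lay within 1 kb of a neighbouring gene's 5′ end, among them those of Ndufb9 with Tatdn1, Psmb3 with Pcgf2 and Cdc45 with Ufd1.

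Genes of B cells and of immune signalling were bound more often than other genes. Of the 30 genes of B cell identity and signalling, 21 (70.0%, 95% exact interval 50.6% to 85.3%) had a promoter peak, against 40.3% of other genes (Fisher's exact test, adjusted p = 0.00172, odds ratio 3.46). The strongest were at Bank1, a B cell scaffold protein gene (signal 323), the kinase gene Lyn (274), Cd79b of the B cell receptor (257), Cd37 (187) and Ebf1, a B cell transcription factor gene (137). Spib (110), Cd79a (93.3), Cr2 (89.8), Ms4a1 (67.4), Tnfrsf13c (63.5), Cd72 (57.5) and Blk (53.3) followed. Signals were lower at Cd40 (48.4), Pou2f2 (46.7), Blnk (42.5), Plcg2 (41.8), Ptpn6 (35.8), Btk (23.8) and Pax5 (16.0). Of these, the peak at Ptpn6 had no entry within 100 bp in either replicate's relaxed list, those at Blnk and Pax5 none in replicate 1, and that at Btk none in replicate 2. No promoter peak was found at Bach2, Cd22, Cd38, Fcrla, Ikzf1, Ikzf3, Pou2af1, Syk or Vpreb3. Interferon signalling genes were bound in 23 of 29 cases (exact test, adjusted p = 5.60e-05), with the strongest peaks at the receptor gene Ifnar1 (512) and the kinase genes Tyk2 (500) and Tbk1 (353), then Irf2 (226). Genes of class switching and double-strand break repair were bound in 22 of 27 cases (exact test, adjusted p = 3.55e-05), led by Dclre1c, the Artemis nuclease gene (425), Xrcc4 (269), Mre11a (253) and Shld1 (229). Mad2l2 and Trp53bp1 had no promoter peak. Antigen presentation genes were bound in 14 of 18 cases (exact test, adjusted p = 0.00335), with lower signals, at most 154 at H2-D1, 102 at Psmb8, 66.8 at Cd74 and 57.8 at H2-DMb1. In the stronger 50% of peaks antigen presentation no longer passed (exact test, adjusted p = 0.335). The mm9 list with GENCODE start sites ended the call for interferon signalling (odds ratio 1.97; exact test, adjusted p = 0.0968). Within strata of equal promoter CpG content on that list, its odds ratio was 2.35, still without a call. The call for class switching and repair ended there, with the odds ratio going from 3.44 to 1.81. The B cell list went up from 3.27 on the mm9 list without strata to 7.88 within them, and antigen presentation from 4.82 to 10.2.

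Genes of other cell types were bound less often than other genes. Of 18 erythroid and megakaryocyte markers, 0 had a promoter peak (upper exact limit 18.5%; Fisher's exact test, adjusted p = 0.000216). The only bound hepatocyte marker of 20 was Apoa2 (signal 80.4), whose peak also lay at Tomm40l, and the only bound neuron marker of 20 was Syp (31.4). Skeletal muscle markers were bound in 2 of 20 cases, Actn3 (403), whose peak also lay at Zdhhc24, and Mylpf (109), whose peak also lay at Tbc1d10b. The adjusted p was 0.00124 for the hepatocyte and neuron lists and 0.00609 for the muscle list (exact test). T cell markers were bound in 4 of 24 cases, Cd5 (79.3), Cd247 (31.1), Gata3 (29.5) and Cd2 (16.9), and myeloid markers in 3 of 20, Cd68 (76.3), Tlr2 (64.9) and Cebpe (51.2), with an adjusted p of 0.0231 for both lists (exact test). Olfactory and vomeronasal receptor genes were bound in 3 of 1448 cases, Vmn1r4, whose peak also lay at Nt5c3, Olfr1260 and Olfr462 (exact test, adjusted p = 7.1e-332). Within strata of equal promoter CpG content, on the mm9 list, the calls for T cell, myeloid, erythroid, hepatocyte and muscle markers ended. The odds ratio went from 0.245 without strata to 0.624 for T cell and from 0.107 to 0.336 for erythroid markers. For hepatocyte markers 0 of 20 genes were bound on that list, so the odds ratio within strata was 0 and the call ended without a smaller difference. The myeloid and muscle calls had already ended on the mm9 list without strata. The neuron and receptor lists stayed below other genes there, with odds ratios of 0.0768 and 0.00724. With start sites widened to 2 kb the T cell, myeloid and muscle calls also ended, in the stronger 50% of peaks the myeloid call did (odds ratio 0.365, against 0.261 before), and without chromosome 11 the T cell call did (0.341, against 0.295 before).

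**Figure D2:**
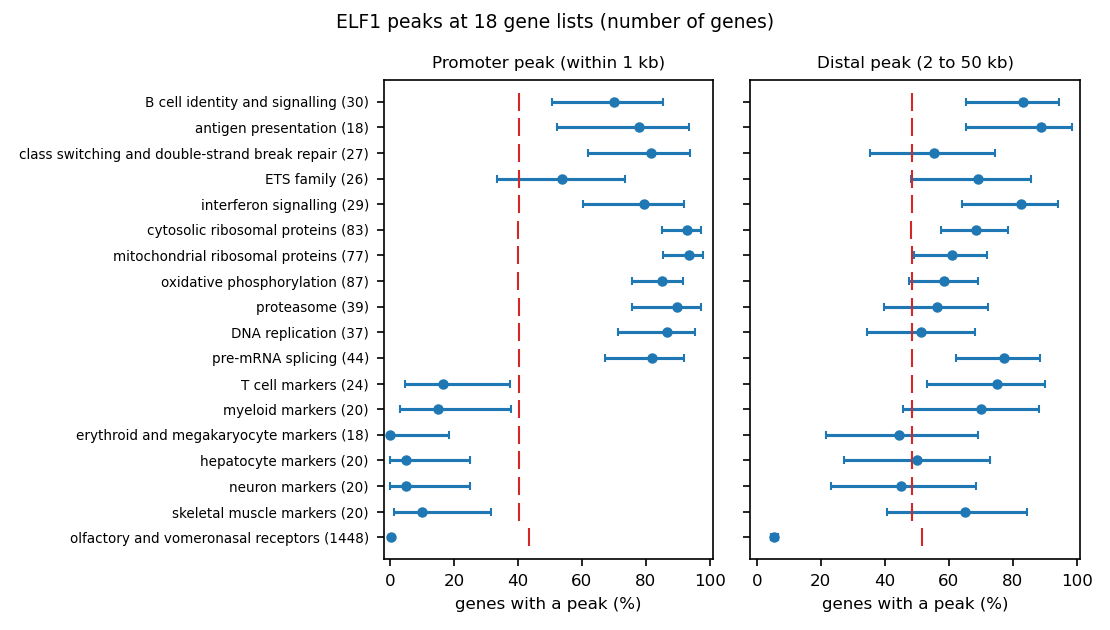
Share of each gene list with an optimal ELF1 peak within 1 kb of the 5′ end (left) or 2 to 50 kb from it and over 2 kb from every start site (right). Points are shares with 95% exact intervals, and red marks are the shares of all other protein-coding genes, about 40.1% to 43.4% on the left and 48.4% to 51.7% on the right.

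ELF1 peaks were found at the promoters of ETS family genes, its own among them. Elf1 had a promoter peak of signal 298 on chromosome 14 from 79481623 to 79481824, with the summit 544 bp from the 5′ end at 79481174, and signals of 109 in replicate 1 and 190 in replicate 2. The peak also lay within 1 kb of the start of the neighbouring gene Wbp4. Gabpa had the strongest peak of the family (358). Spi1, which encodes PU.1 (165), Etv6 (143), Elk3 (130), Spib (110), Elk4 (108), Etv3 (104) and Elf3 (54.4) followed. Ets2 (37.7), Spic (37.6), Etv4 (34.0), Etv5 (32.4) and Elf2 (19.1) had weaker peaks. Ehf, Elf4, Elf5, Elk1, Erf, Erg, Ets1, Etv1, Etv2, Fev, Fli1 and Spdef had none. The 14 bound of 26 (53.8%) did not differ from the 40.3% of other genes (Fisher's exact test, adjusted p = 0.167), although the list passed with the conservative peaks (odds ratio 2.43) and with replicate 1 alone (2.32).

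Distal peaks gave another ranking of the gene groups. Of the B cell genes 25 of 30 (83.3%) had a peak 2 to 50 kb away, against 48.4% of other genes, including Ikzf1, Ikzf3, Syk, Cd22, Cd38, Fcrla, Pou2af1 and Vpreb3, which had no promoter peak. Antigen presentation genes had such peaks in 16 of 18 cases, among them Ciita, H2-Aa, H2-Ab1 and H2-K1, unbound at the promoter. Interferon signalling genes had them in 24 of 29, splicing genes in 34 of 44 and cytosolic ribosomal protein genes in 57 of 83. The adjusted p was 0.000852 for the B cell and splicing lists, 0.0016 for antigen presentation, and 0.000878 for interferon signalling and cytosolic ribosomal proteins (Fisher's exact test, two-sided, Benjamini-Hochberg over 18 lists). Because 1 5′ end per gene was used, a distal peak can also lie at an alternative start site, which was not checked. Genes close together can count the same distal peak, so these p-values are too small to an unknown degree. H2-DMb1 and Psmb8 of the antigen presentation list, for example, start at 34153191 and 34198195 on chromosome 17. T cell markers, few of which were bound at the promoter, had a distal peak in 18 of 24 cases (exact test, adjusted p = 0.0325), among them Cd3d, Cd3e, Cd3g, Cd4, Lck and Tcf7. Receptor genes had one in 79 of 1448 (5.46%; exact test, adjusted p = 9.17e-304). The T cell call ended in the stronger 50% of peaks (odds ratio 1.16), with 100 kb (2.74), with the conservative peaks (2.77) and with either replicate alone (2.42 to 2.50), against 3.198 in the main setting and 3.98, with the call kept, when stratified by promoter binding. The call for splicing ended at 20 kb (1.21), and that for cytosolic ribosomal proteins ended when genes were stratified by promoter binding (1.43).

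Divergent promoters, where a pair of protein-coding genes start head to head within 1 kb, were bound more often than others. Of 1435 genes with such a partner 1229 (85.6%, 95% exact interval 83.7% to 87.4%) had a promoter peak, as at Gabpa with Atp5j and Mrpl10 with Lrrc46, whose peaks lay within 1 kb of both 5′ ends. Of 19122 other genes 7064 (36.9%, 36.3% to 37.6%) had one (Fisher's exact test, two-sided, odds ratio 10.2, p = 1.17e-296). A peak near either start site can count for both genes of a pair, which raises this share. With each of 717 pairs counted once, 617 (86.1%) had a peak at 1 gene or both, against 60.2% on average and 65.8% at most for 1000 sets of random pairs of other genes (permutation p = 0.001, the smallest these sets can give). The odds ratio was then 4.07. On the mm9 list the odds ratio was 6.67, and 3.16 within strata of equal promoter CpG content.

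The sequence comparison asked whether the peaks held the ETS site, and was run on the mm9 list. The 8-mer CCGGAAGT lay within 50 bp of the summit in 1535 of 18804 peaks (8.16%, 95% exact interval 7.78% to 8.56%), against 0.218% of windows 500 bp downstream and 0.165% upstream. In 1535 peaks it was in the summit window alone and in 41 in the downstream window alone (exact McNemar test, two-sided, p = 1.7e-393). Of 899 reorderings of the same bases with the same number of CpG, the median was found in 0.138% of summit windows, and the highest, CGGAAGTC, which shares the core, in 3.10%. Of all sites within 500 bp of a summit, 73.4% lay within 50 bp, against 10.1% for an even spread. At Fam172a the summit window held the site in AGACCCGGAAGTGCAA on mm9 chromosome 13 from 77847966 to 77847981, with the summit 6 bp from a start site. At Gatad2a, in the untranslated first part of the gene, it was TCACACTTCCGGGTTG on chromosome 8 from 72520185 to 72520200. At Sec31a it was CGGCACTTCCGGGAGC on chromosome 5 from 100845308 to 100845323, 5 bp from the summit, and at Tfg CAGCACTTCCGGTTTT on chromosome 16 from 56717705 to 56717720. The windows of Edem2, Ciao3 and Elf1 held no site of the wider form SCGGAAGY.

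Stronger peaks held the site more often. It was present in 25.1% (23.1% to 27.1%) of the strongest decile of the mm9 peaks and in 1.76% (1.21% to 2.46%) of the weakest. The Spearman correlation between decile and share was -0.988 (permutation test, 100000 resamples, two-sided, p = 4e-05).

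**Figure D3:**
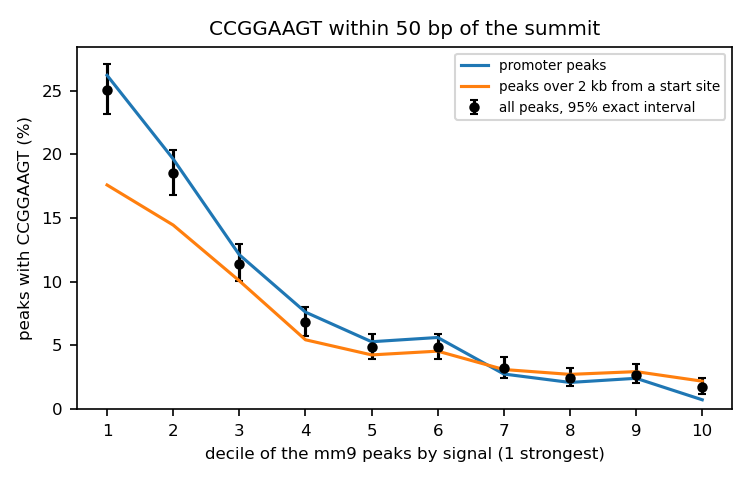
Share of the mm9 peaks with CCGGAAGT within 50 bp of the summit, by decile of signal. Points are all peaks with 95% exact intervals, and lines are promoter peaks and peaks over 2 kb from a start site; the share of all peaks fell from 25.1% to 1.76%.

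Promoter and distal peaks differed in the flank of the ETS site. CCGGAAGT was in 11.4% of 9173 promoter peaks and 4.94% of 8660 peaks over 2 kb from every start site (Fisher's exact test, odds ratio 2.47, p = 1.04e-56), 42.7 and 37.2 times its share beside the peak. Much of the difference went with signal, since within deciles of signal the odds ratio was 1.251. The site was in 26.2% of promoter and 17.6% of distal peaks in the strongest decile, and in 0.730% and 2.19% in the weakest. It was more frequent at promoters in deciles 1 to 6 and at distal peaks in deciles 7 to 10. CAGGAAGT, a form chosen after its values were seen, went the other way, with 6.66% of promoter and 20.6% of distal peaks (Fisher's exact test, odds ratio 0.276, p = 1.23e-168), and an odds ratio of 0.248 within deciles of signal. The shares were 10.1 and 24.9 times those beside the peak. Among all 8-mers ranked by the excess of their count over that beside the peak, divided by the square root of the latter plus 1, the first at promoters was CCGGAAGT. The first at distal peaks were AGGAAGTG, found in 20.3% of distal summit windows against 0.791% beside them, and CAGGAAGT. Of the panel of 12 fixed words, 11 were in more summit than downstream windows. GAGGAAGT, the PU.1 class word, was in 3.90% of promoter and 10.2% of distal peaks, 6.28 and 17.4 times its share beside the peak. It is also 1 of the 16 forms of the ETS site, so it does not separate PU.1 from ELF1. The SP/KLF class word GGGCGG was in 34.6% of promoter peaks, 3.17 times its share beside them, and the CRE word TGACGTCA in 1.97%, 16.5 times. In distal peaks the AP-1 word TGASTCA was in 5.58% (3.03 times), the CTCF class word CCACNAGG in 4.11% (2.77 times) and the RUNX word TGTGGTT in 3.86% (1.54 times). At promoters the AP-1 word (exact McNemar test, adjusted p = 0.361), the RUNX word (0.315) and the IRF word GAAANNGAAA (0.589) did not pass. In distal peaks the IRF word did, at 2.19% and 1.58 times its share beside them (exact McNemar test, adjusted p = 2.92e-05). The NFY word CCAAT was more frequent than beside the peak at promoters, 1.62 times, and less at distal peaks, 0.899 times (exact McNemar test, adjusted p = 7.55e-35 and 0.02). The E2A class word CAGGTG was the exception over all peaks, at 7.37% (exact McNemar test, adjusted p = 0.281). It was less frequent than beside the peak at promoters, 0.719 times, and more frequent at distal peaks, 1.17 times (exact McNemar test, adjusted p = 1.6e-09 and 0.000307).

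**Figure D4:**
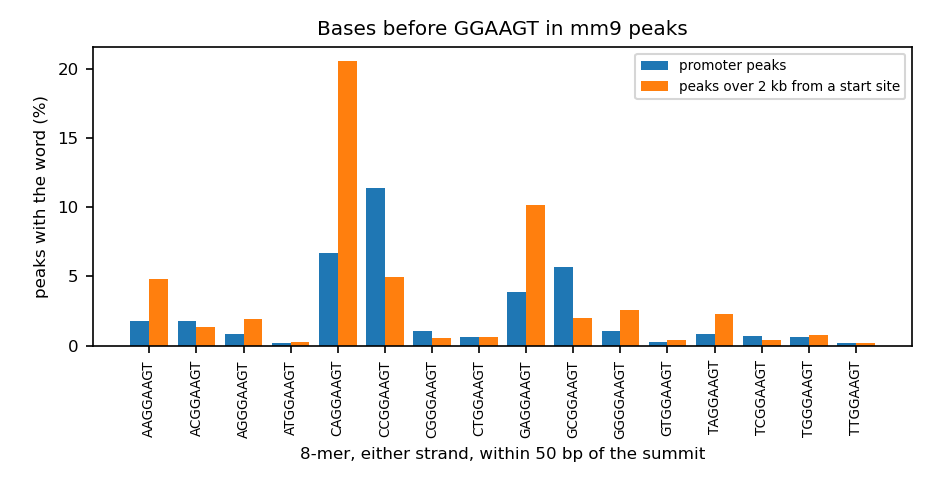
Share of 9173 promoter and 8660 distal mm9 peaks with each of 16 forms of the ETS site, 2 variable bases followed by the shared core, within 50 bp of the summit, on either strand. CCGGAAGT was the most frequent form at promoters (11.4%) and CAGGAAGT at distal peaks (20.6%).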

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

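The test of mm10 entries at the Y genes was chosen only after its result was seen. The mm9 list held 2 peaks on chromosome Y, although the line is labelled female, a signal outside the comparisons above. One lay at the start of Eif2s3y, from 346943 to 347142, with a signal of 165, and the other at Ddx3y, from 622809 to 623184, with 37.9. Reads of X-linked copies placed on Y are argued against, because the longest alignment of either peak at 95% identity or more outside Y was 0 bp, and the best match on X had 82.1% identity over 78 bp. A Y chromosome in the cultured cells could not be decided: 0 entries of the 3 relaxed mm10 lists lay within 1 kb of either start site, while 95.4% and 94.4% of promoters bound at least as strongly in the mm9 list had a pooled entry. A difference between the reads behind the mm9 and mm10 lists stays open and untested.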

How the results depend on the processing

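The settings that drop chromosome 11 or peaks beside a stronger one, the mm9 list with GENCODE start sites, signal deciles for the ETS site at promoter against distal peaks, divergent pairs counted once, and replicate 1 against replicate 2 without the optimal list (65.3%), were added after seeing the data. Replicate agreement stayed above the shifted sets under 9 alternatives, from 55.4% at 50 bp to 85.4% with all deposited peaks. However, all but replicate 1 against replicate 2 start from peaks called on both replicates together. The promoter share stayed above the shifted sets under 11 alternatives, from 27.7% at 500 bp to 48.8% on the mm9 list. It was 33.0% to 33.6% with either replicate alone. The share of optimal peaks met by conservative ones was 78.3% with reciprocal overlap of 50% and also with summits within 100 bp, since both counts were of the 22761 identical peaks.

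Of 18 lists, 17 passed at promoters, and 14 to 18 under every alternative except CpG strata on the mm9 list, with 10 (14 on that list without strata, where the myeloid, muscle and interferon calls had already ended). Both lists that changed direction did so under CpG strata, with odds ratios of 1.73 for myeloid and 1.14 for muscle markers. Distal lists passed in 6 to 10 of 18 cases, and 7 to 8 with either replicate alone. Lists that changed direction had not passed in the main setting. At 20 kb the odds ratios were 0.743 for class switching, 0.650 for hepatocyte and 1.40 for neuron markers. At 100 kb DNA replication had 0.898. Stratified by promoter binding, class switching had 0.913, oxidative phosphorylation 0.996, proteasome 0.869, DNA replication 0.722, erythroid 1.24 and neuron markers 1.22. Hepatocyte markers had 0.581 in the stronger 50% of peaks, and neuron markers 1.04 without chromosome 11. With either replicate alone, DNA replication had 0.845 to 1.35 and hepatocyte markers 0.995 to 1.03, the lower value with replicate 2 alone. The cause was not tested for any of these. Divergent promoters kept their direction and call under 9 alternatives, the ETS site under 6, the trend with rank under 3 and the panel count of 11 words under 3. Within signal deciles the odds ratio of promoter to distal peaks was 1.251 for CCGGAAGT and 0.248 for CAGGAAGT, with direction and call kept for the pooled ratio. For CCGGAAGT the direction was reversed in deciles 7 to 10.

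Motif results with the conservative list and with each replicate alone were not run, because no mm10 sequence was used here. The unknown read depth limits statements on weak peaks.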

Other observations

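Binding followed the CpG content of promoters. On the mm9 list, 3.17% of genes in the lowest decile of the CpG observed to expected ratio had a promoter peak, 27.7% in the fifth decile and 65.7% in the highest. Of the mm9 peaks 48.8% lay within 1 kb of a start site, 23.1% in introns and 25.5% between genes, while 1.15% lay in coding exons, 0.979% in untranslated regions and 0.484% in non-coding exons. By gene, 86.8% of promoters bound in the mm9 list were also bound in the mm10 optimal list, and the signals of genes bound in both had a Spearman correlation of 0.946 across genes.

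The shoulder test of the weakest decile and the comparison with chromosome 7 were chosen only after their results were seen. Chromosome 11 held 27.5 optimal peaks per Mb, against a median of 11 and at most 14.8 on the other 18 autosomes, and 24 of its 25 segments of 5 Mb were above the median of the other autosomes in weak entries. Gene density was not excluded by the bound set beforehand. Chromosome 7 had 13.2 protein-coding genes per Mb against 12.9, and chromosome 11 held 2.27 times its optimal peaks per Mb. So a like number of genes went with fewer peaks on chromosome 7. That comparison cannot decide, since chromosome 11 had already been seen to exceed every other autosome. The chromosomes also differed in the share of promoters bound, 33.3% on chromosome 7 against 51.6%. In sequence over 50 kb from every gene, chromosome 11 held 75.1 weak entries per Mb. The other autosomes had a median of 32.2 and at most 62.8, and chromosome 7 had 27.0. This excess far from genes argues against gene density as the whole cause for weak entries. The density was 1.19 times that of the next highest autosome, chromosome 16. That is close to but under the bound of 1.2 set beforehand for excluding gene density. Extra copies of chromosome 11 in the line may contribute and cannot be told apart from other causes: promoter peaks there had a median signal 1.16 times that of the other autosomes, between the bounds of 1.1 and 1.2 set beforehand and below chromosome 16 (112 against 129), and no read counts were used here to decide it.

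Chromosome X held 2.36 optimal peaks per Mb and 2.78 weak entries per Mb of gene-free sequence, against an autosomal median of 32.2 outside chromosome 11 for the latter. On chromosome 3, 5 neighbouring segments of 5 Mb toward its far end, picked after their values were seen, held 231 to 350 weak entries per Mb, against a median of 88.1 in the 26 segments before them.

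The weakest decile of the optimal peaks lay at promoters more often than the ninth, 24.6% against 18%. Shoulders of stronger peaks are a candidate explanation, since 55.3% of the weakest decile had a stronger optimal peak within 400 bp, against 5.53% of the ninth. Separate weak sites found in both replicates could not be decided. A summit within 50 bp in both full replicate lists was 0.356 times as frequent as in the ninth, 18.5% against 52.0%, below the bound set beforehand. But this share fell with signal over all deciles, so weaker separate sites would also be found less often. The median signal was 12.9 in the weakest decile and 21.5 in the ninth. Without peaks beside a stronger one, 20.9% of the weakest decile and 16.5% of the ninth lay at promoters, so part of the excess stays open. No biological explanation was tested.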
